A study of Homo sapiens with 12 samples.

How the data were processed

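Total RNA of HepG2 cells in 4 media was turned into 12 QuantSeq libraries (3 per medium), which sequence the 3′ end of messenger RNA. The submitters' processing notes name FastQC 0.72, cutadapt 1.16, STAR 2.7.5b, featureCounts 1.6.3 and limma 3.40.6, and the human genome build hg19 (GRCh37), and the gene annotation is not given in the sources used here. The values deposited by the authors are raw counts per gene, whole numbers without normalization. The deposited table had 10994 entries, and 53 Ensembl identifiers occurred several times with identical counts, so 54 surplus entries were dropped and 10940 genes kept. In every gene the third-highest library had at least 4.04 CPM, so genes with low counts had been removed before deposit. Of the entries, 506 had no symbol, and 255 genes without one were named from the reference by identifier. Genes are given by symbol and, for the main ones, by Ensembl identifier. No coordinates are given, since the build of the counts differs from that of the reference at hand. Total counts per library ran from 1562125 to 2384090.

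Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at its default settings (minimum count 10, minimum total count 15), which removed 481 genes and left 10459, and libraries were scaled with TMM factors. One quasi-likelihood model with the 4 media was fitted to all 12 libraries (8 residual degrees of freedom). The 3 medium coefficients were tested together, and then 4 main and 2 secondary comparisons were tested, all two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison were called, without a minimum fold change, and the number with an absolute log2 fold change of at least 1 is given beside it. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so adjusted p-values rest on the model's spread shared across genes. Standard errors were derived from the quasi-likelihood test, as the absolute log2 fold change divided by the square root of its F statistic. Principal components were computed on log2 CPM with a prior count of 2.

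Fixed before the data were examined were the comparisons, the alternatives, 31 gene lists and the rule for named genes. That rule names 6 iron genes in every comparison. It then takes called genes with a mean of at least 5 CPM and no overlap between the libraries of the media compared, the 8 with the highest and the 8 with the lowest log2 fold change in a main comparison (4 and 4 in a secondary one), and up to 4 members with the lowest p of each list described. Not every gene that the rule names is described. Lists with at least 5 measured members, 27 in all, were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, fry, and counts of members called over all genes and adjusted over the list alone. The median, the mean and the camera direction of a called list differed in sign in 0 of the called lists of any comparison. Some lists share members, such as TF in the iron and hepatocyte lists and GDF15 and SESN2 in the ATF4 and p53 lists.

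The alternatives were RLE factors, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, 10 counts in every library of a group, a mean of 5 CPM, a replicate block (the replicate number of the labels), a library-number block (3 runs of 4 consecutive library numbers, 85 to 88, 89 to 92 and 93 to 96), each library left out in turn, and only the 6 libraries compared. Leaving out Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2 together, and camera with the library-number block, were chosen after seeing the data. For the Plasmax-TE+Fe libraries replicate number and run differ, with replicate 1 in the last run, replicate 2 in the first and replicate 3 in the middle one. Overlaps between comparisons that share libraries were set beside 20 simulations of unchanged groups. The tests were tried on simulated data for Plasmax-TE+Fe against Plasmax-TE with 200 changed genes among 10459. There edgeR made 8 false calls (6.84% of its calls), and its test of the 4 media together recovered 113 of the 200. Camera with the preset correlation called a list of 30 genes shifted by 0.5 (adjusted p = 1.3e-11) and 0 of 20 unchanged lists. Correlation between genes was not varied there, while estimates in the real lists of this comparison reached 0.44 (nuclear-encoded respiratory chain subunits). How often camera calls unchanged lists with correlated members is therefore not known from these data.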

Results

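HepG2 cells, an established human line derived from a liver cancer, were switched from their maintenance medium to 1 of 4 media, and messenger RNA was counted from the 3′ end of transcripts. The media were EMEM (Eagle's minimum essential medium, the maintenance medium), Plasmax (a medium whose nutrients follow human plasma), Plasmax prepared without its trace elements (Plasmax-TE), and the latter with iron put back (Plasmax-TE+Fe). All contained 10% heat-inactivated fetal bovine serum. Cells were switched 24 h after seeding, received fresh medium after 48 h and were harvested at 96 h. Each medium had 3 libraries, 12 in all. Total counts were 1605043, 2384090 and 2197949 for EMEM and 1562125, 1914442 and 2227849 for Plasmax. They were 1752389, 2228520 and 1910876 for Plasmax-TE and 2379065, 1849229 and 2013357 for Plasmax-TE+Fe. At these depths 1 count was worth between 0.419 and 0.640 CPM (counts scaled to the same total in every library), so changes of genes below a few CPM were not detectable unless large. Levels below are mean CPM ± SD over the 3 libraries of a medium (n = 3), and log2 fold changes are given ± SE.

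Of 10459 genes tested, 1879 (18.0%) differed among the 4 media in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2835 did so with a block for the run of library numbers. Principal component 1, with 34.1% of the variance of log2 CPM, placed the EMEM libraries between -33.5 and -27.3 and the Plasmax libraries between 30.5 and 35.2, with the media lacking trace elements in between. Component 2, with 17.6%, set Plasmax-TE replicate 1 (-35.5) and Plasmax-TE+Fe replicate 2 (-32.0) apart from all other libraries, which lay between -8.1 and 19.6. These libraries carry the consecutive numbers 87 and 88. In them the ATF4 target ASNS, asparagine synthetase, stood at 163 and 219 CPM against 418 to 700 CPM in the other libraries of the same media. The small nucleolar RNA SNORD13 stood at 1020 and 543 CPM against 61.1 to 169 CPM (both genes were chosen after their values were seen). Nothing in the labels says that the libraries of a medium came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

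**Figure D1:**
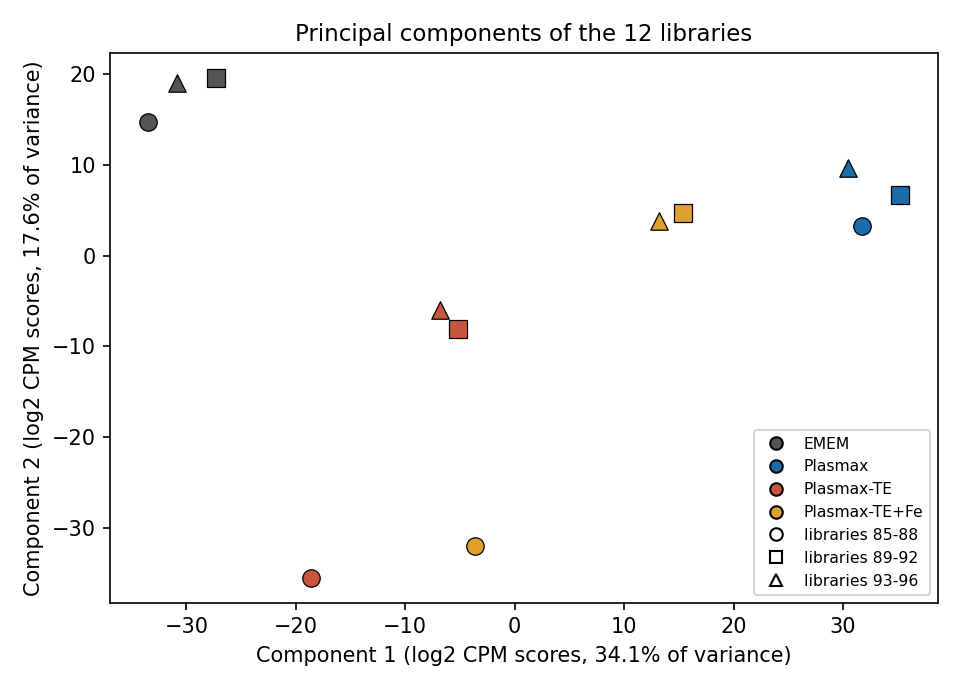
Scores of the 12 libraries on principal components 1 (34.1% of the variance) and 2 (17.6%) of log2 CPM. Colour gives the medium and marker shape the run of library numbers; Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2, both from libraries 85 to 88, lie near the bottom at -35.5 and -32.0.

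Plasmax was set against EMEM to see how a plasma-like medium changed the transcripts of cells kept until then in the maintenance medium. TXNIP (ENSG00000265972), which encodes an arrestin that restrains glucose uptake, rose from 7.16 ± 1.21 CPM in EMEM to 474 ± 114 CPM in Plasmax, a log2 fold change of 6.01 ± 0.25 (64.5-fold). AREG (ENSG00000109321), a ligand of the epidermal growth factor receptor, rose from 39.9 ± 11.2 to 682 ± 145 CPM, and CYP1A1 (ENSG00000140465), a target of the aryl hydrocarbon receptor, rose by 3.63 ± 0.31. The liver secretory genes ALB and AFP, for albumin and alpha-fetoprotein, fell by 2.20 ± 0.11 and 2.81 ± 0.15. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 3.8e-12 for TXNIP, 2.3e-06 for AREG, 1.1e-07 for CYP1A1 and 1.1e-10 for ALB and AFP. TXNIP and AREG did not overlap between the libraries of these media, so each of the 3 runs of library numbers necessarily showed the same direction.

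By the same test 2233 genes (21.4%) differed between Plasmax and EMEM, 1035 of them higher and 1198 lower in Plasmax, and 916 differed by a log2 fold change of at least 1. With the library-number block the count was 2907. Among the other genes with the largest rises were EMP1, an epithelial membrane protein (5.30 ± 0.50), EREG, a further ligand of the epidermal growth factor receptor (4.51 ± 0.68), and CSTA, the protease inhibitor cystatin A (4.30 ± 0.28). They were followed by TSC22D3, a glucocorticoid-induced leucine zipper protein (4.03 ± 0.39), and RNF125, a ubiquitin ligase (3.66 ± 0.40). ARRDC4, an arrestin related to TXNIP, went from 0.570 ± 0.654 to 8.72 ± 4.38 CPM. EMP1, EREG and ARRDC4 had at most 3 counts in any EMEM library, which leaves the size of their rise uncertain. Among the largest falls were those of HAL, histidine ammonia-lyase (22.1 ± 11.5 to 0.675 ± 0.699 CPM), SULT2A1, a steroid sulfotransferase (-4.01 ± 0.21), TNS1, the focal adhesion protein tensin (-3.83 ± 0.46), and AGXT, the peroxisomal enzyme that detoxifies glyoxylate (-3.80 ± 0.35). Next were LOX, lysyl oxidase (-3.69 ± 0.41), ANGPTL1 (-3.49 ± 0.34) and the peptidase NAALADL1 (-3.40 ± 0.32).

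Genes of cholesterol synthesis fell together. Of 22 measured members 19 fell and 3 did not pass the test (20 fell adjusted over the list alone), with a median log2 fold change of -1.49. SQLE, squalene epoxidase, fell by 2.32 ± 0.23, MSMO1 by 1.81 ± 0.17 and FDFT1, squalene synthase, by 1.55 ± 0.16. In fatty acid synthesis 8 of 14 members fell and 1 rose (10 and 1 adjusted over the list alone), among them the desaturases FADS2 (-2.52 ± 0.34) and SCD (-1.32 ± 0.14). In fatty acid oxidation and ketogenesis 10 of 17 members fell and 1 rose, as adjusted over the list alone, with FABP1, the liver fatty acid binding protein, at -2.03 ± 0.16 and HADH at -1.40 ± 0.22. In drug and bile acid metabolism 7 of 11 members fell and 1 rose (9 and 1 adjusted over the list alone). SULT2A1 and NR0B2, a nuclear receptor that represses bile acid synthesis (-1.94 ± 0.20), fell, and CYP1A1 rose. The list of iron uptake, storage and export had 7 of 21 members lower, as adjusted over the list alone, including TF, transferrin (-2.05 ± 0.16), CP, the ferroxidase ceruloplasmin (-1.99 ± 0.26), and NCOA4, the ferritin autophagy receptor (-1.11 ± 0.13). Camera's adjusted p for these 5 lists was 4.2e-27, 6.0e-06, 2.1e-05, 2.5e-07 and 0.0035 in this order. With an estimated correlation the values were adjusted p = 0.0076, 0.0076, 0.042, 0.0076 and 0.042, so these 5 calls held. With both the block and an estimated correlation the iron call was lost (adjusted p = 0.050) and the other 4 held.

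Another 6 lists were called by camera with its preset correlation but not with an estimated correlation alone. Hepatocyte secreted proteins and markers had 19 of 33 members lower and 3 higher (24 and 4 adjusted over the list alone), with TTR, transthyretin, at -2.19 ± 0.16 and the coagulation factor F10 at -1.79 ± 0.19 (adjusted p = 0.061 with an estimated correlation, and adjusted p = 0.023 with an estimated correlation and the block). Of the targets of hypoxia-inducible factor (HIF), 18 of 30 fell (21 adjusted over the list alone), including P4HA1, a collagen prolyl hydroxylase (-1.85 ± 0.21), and BNIP3, a mitophagy receptor (-1.63 ± 0.21), with adjusted p = 0.19 with an estimated correlation. Glycolysis had 6 of 14 members lower (7 adjusted over the list alone), among them the lactate exporter SLC16A3 (-1.23 ± 0.16) and aldolase C, ALDOC (-2.20 ± 0.33), with adjusted p = 0.33 with an estimated correlation. G2/M and mitosis genes were lower in 12 of 31 cases (16 adjusted over the list alone), such as MKI67 (-1.01 ± 0.20) and AURKA (-1.05 ± 0.20), with adjusted p = 0.29 with an estimated correlation. The urea cycle and amino acid catabolism list had 6 of 20 members lower and 2 higher, as adjusted over the list alone (adjusted p = 0.061 with an estimated correlation). Of the p53 targets 9 of 24 rose and 1 fell, as adjusted over the list alone. The cyclin-dependent kinase inhibitor CDKN1A rose by 1.45 ± 0.22 and ZMAT3 by 1.01 ± 0.16, while CCNG1 fell by 0.80 ± 0.18 (adjusted p = 0.10 for the list with an estimated correlation). Of the lists that were not called, camera's adjusted p was 0.17 for acute phase and complement, nuclear-encoded respiratory chain subunits and nucleotide synthesis. It was 0.23 for ATF4 and the integrated stress response, 0.25 for immediate early and heat shock genes and 0.31 for hepcidin and BMP-SMAD targets. Among the other values were 0.67 for S phase and DNA replication, 0.76 for NRF2 targets and for metallothioneins and zinc transport, 0.77 for lysosome and autophagy, 0.84 for the unfolded protein response, and 0.88 for heme synthesis and iron-sulfur assembly and for interferon-stimulated genes.

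Among the iron genes named in advance, TFRC (ENSG00000072274), the transferrin receptor, fell from 154 ± 17.9 CPM in EMEM to 83.8 ± 10.8 CPM in Plasmax (log2 fold change -0.88 ± 0.23). HAMP (ENSG00000105697), the iron-regulatory hormone hepcidin, fell from 45.8 ± 12.4 to 7.05 ± 1.07 CPM (-2.71 ± 0.32). The ferritin chains FTH1 (0.30 ± 0.13) and FTL (0.34 ± 0.17), the iron exporter SLC40A1 (-0.60 ± 0.32) and the iron importer SLC11A2 (-0.08 ± 0.16) did not pass. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0087 for TFRC, 5.4e-06 for HAMP, 0.11 for FTH1, 0.16 for FTL, 0.19 for SLC40A1 and 0.76 for SLC11A2. With the library-number block FTH1 passed at adjusted p = 0.041.

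**Figure D2:**
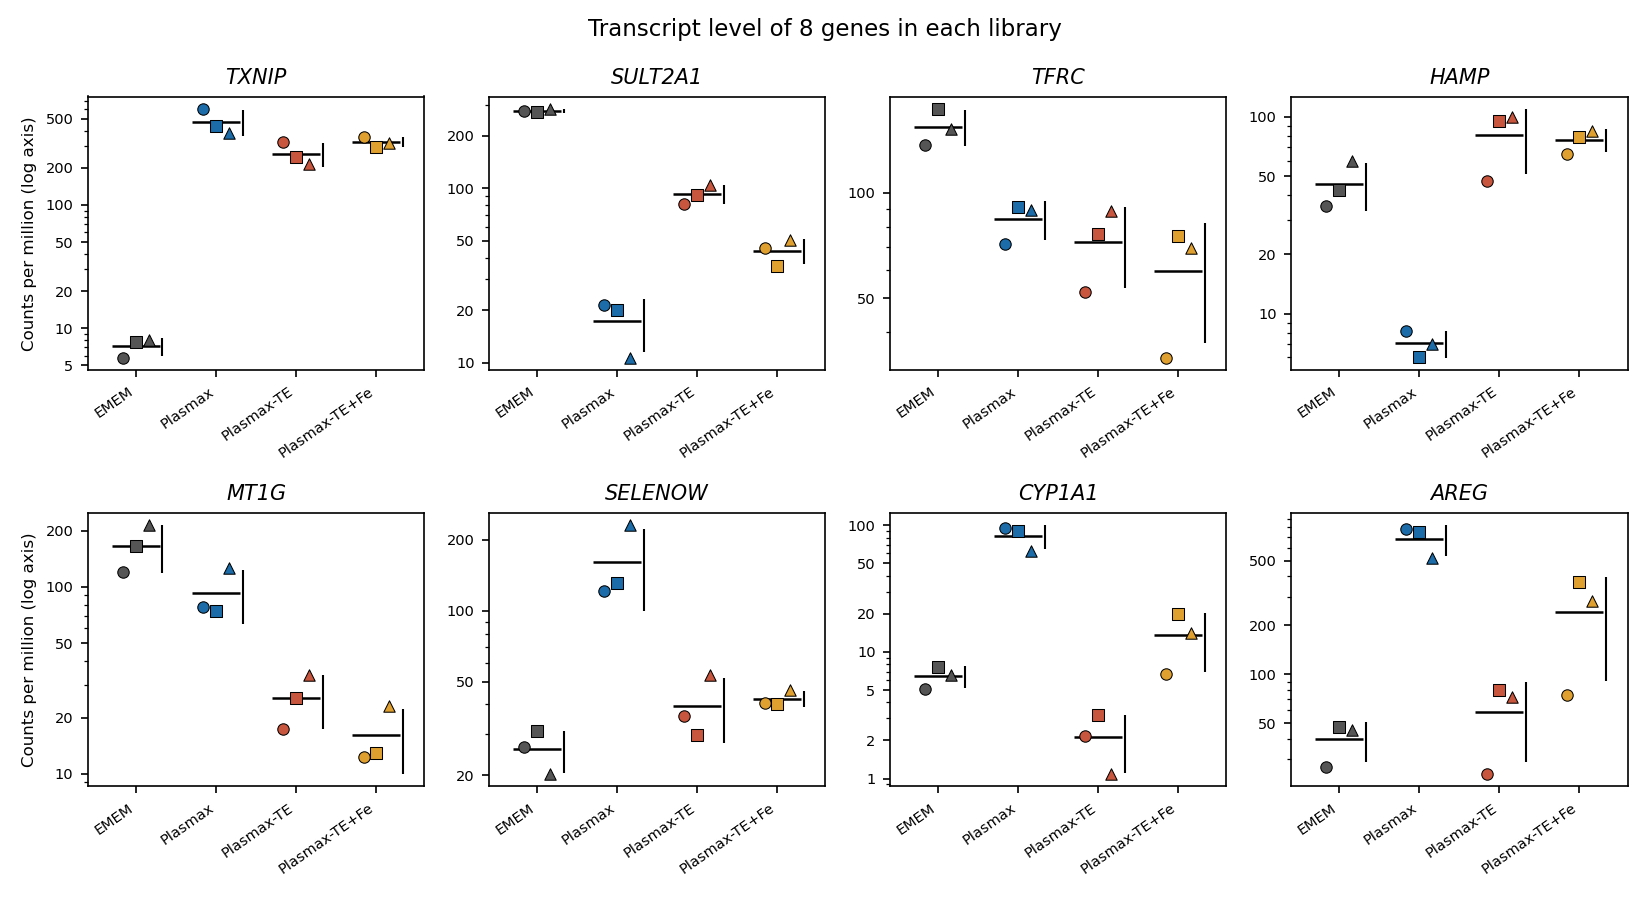
Level of 8 genes in each library, in CPM on a log axis, by medium. Marker shape gives the run of library numbers (circles 85 to 88, squares 89 to 92, triangles 93 to 96), horizontal lines the mean and vertical lines ± 1 SD (n = 3); HAMP averages 7.05 CPM in Plasmax and 80.6 and 76.4 CPM in Plasmax-TE and Plasmax-TE+Fe, whereas CYP1A1 averages 82.8, 2.13 and 13.6 CPM in these media.

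Plasmax-TE was set against Plasmax to see what followed from leaving out the trace elements. HAMP rose from 7.05 ± 1.07 CPM to 80.6 ± 29.1 CPM, a log2 fold change of 3.52 ± 0.31 (11.5-fold). Metallothioneins, small proteins that bind zinc and copper, fell: MT2A by 2.28 ± 0.24, MT1G (ENSG00000125144) by 1.87 ± 0.28, MT1E by 1.83 ± 0.22 and MT1X by 1.47 ± 0.23. CYP1A1 fell from 82.8 ± 17.6 to 2.13 ± 1.03 CPM (-5.19 ± 0.37) and AREG from 682 ± 145 to 58.9 ± 30.2 CPM (-3.52 ± 0.43). SELENOW (ENSG00000178980), a selenoprotein, fell from 161 ± 61.0 to 39.6 ± 12.3 CPM (-2.04 ± 0.24), while ALB rose by 1.41 ± 0.11. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 8.0e-07 for HAMP, 7.2e-06 for MT2A, 3.0e-04 for MT1G, 8.7e-08 for CYP1A1, 3.9e-05 for AREG, 3.1e-05 for SELENOW and 3.3e-07 for ALB. HAMP, CYP1A1 and AREG did not overlap between the libraries of these media, so they necessarily went the same way in each of the 3 runs.

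That test called 1176 genes (11.2%), 587 higher and 589 lower without trace elements, and 460 with a log2 fold change of at least 1. The count was 1859 with the library-number block and fell to 477 without Plasmax replicate 2, 744 without Plasmax-TE replicate 1 and 780 without Plasmax replicate 1. Other genes with the largest rises were KNG1, kininogen (3.51 ± 0.65), NAALADL1 (2.82 ± 0.33), G6PC, the catalytic subunit of glucose-6-phosphatase (2.66 ± 0.37), the prolactin receptor PRLR (2.64 ± 0.46) and TNFSF10, the death ligand TRAIL (2.45 ± 0.38). SNORD13 (4.29 ± 0.90) and HAL (3.73 ± 1.05) also passed, but both stood highest in Plasmax-TE replicate 1, at 1020 and 23.3 CPM against at most 169 and 4.89 CPM in the other 2 libraries. HAL no longer passed with that library and Plasmax-TE+Fe replicate 2 left out, an alternative chosen after seeing the data (adjusted p = 0.093 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The largest further falls were those of PMAIP1, a pro-apoptotic member of the BCL2 family (-3.54 ± 0.35), EMP1 (-3.50 ± 0.40) and GPRC5A, a retinoic acid-induced receptor (-3.18 ± 0.49). They were followed by DUSP5, a nuclear phosphatase of ERK (-3.02 ± 0.40), EREG (-2.97 ± 0.56) and CDKN2B, a cyclin-dependent kinase inhibitor (-2.76 ± 0.50).

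Camera with its preset correlation called 13 of 27 lists in this comparison, 8 higher and 5 lower, and none of these calls held with an estimated correlation alone. In metallothioneins and zinc transport 6 of 11 members fell and 5 did not pass (7 fell adjusted over the list alone), with a median of -1.23 (adjusted p = 0.099 with an estimated correlation, adjusted p = 0.0088 with an estimated correlation and the library-number block, and adjusted p = 0.027 with an estimated correlation and the 2 libraries that stood apart left out). Hepatocyte secreted proteins and markers had 19 of 33 members higher and 1 lower (22 and 1 adjusted over the list alone), including APOH (1.19 ± 0.15) and the bile acid receptor NR1H4 (1.32 ± 0.21). The list had adjusted p = 0.13 with an estimated correlation and adjusted p = 0.012 when the block was added. Acute phase and complement genes rose in 8 of 16 cases, as adjusted over the list alone, among them the fibrinogen chain FGB (0.95 ± 0.20) and complement C5 (0.99 ± 0.23). This list had adjusted p = 0.15 with an estimated correlation and adjusted p = 0.012 when the block was added. These 3 calls held with both the estimated correlation and the block, and the other 10 did not. HP, FGA, FGG and FGB, which rose, belong to both the hepatocyte and the acute phase list, so these calls are not independent. With an estimated correlation and the 2 libraries that stood apart left out, hepatocyte proteins had adjusted p = 0.12 and acute phase genes adjusted p = 0.16. The acute phase list had a median log2 difference of 0.39 in those libraries from the other 4 of the same media, with 14 of 16 members above 0.

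Cholesterol synthesis had 6 of 22 members higher and 1 lower (12 and 1 adjusted over the list alone), with SQLE at 1.03 ± 0.24 (adjusted p = 0.15 with an estimated correlation). In fatty acid oxidation and ketogenesis 8 of 17 members rose and 1 fell, as adjusted over the list alone. HADH rose by 1.18 ± 0.22 and the lipid droplet protein PLIN2 fell by 0.73 ± 0.19 (adjusted p = 0.13 with an estimated correlation). G2/M and mitosis genes rose in 10 of 31 cases (19 adjusted over the list alone), such as the kinetochore motor CENPE (1.13 ± 0.18) and BIRC5, survivin (0.84 ± 0.19), with adjusted p = 0.15 with an estimated correlation. Iron uptake, storage and export had 6 of 21 members higher, as adjusted over the list alone, among them TF (0.84 ± 0.16), TFR2, the second transferrin receptor (1.12 ± 0.22), and FBXL5, the ubiquitin ligase adaptor that senses iron (1.08 ± 0.29). The iron list had adjusted p = 0.15 with an estimated correlation. Drug and bile acid metabolism had 4 of 11 members higher and 1 lower (7 and 1 adjusted over the list alone), with SULT2A1 at 2.43 ± 0.21. With Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2 left out, camera with the preset correlation no longer called this list (adjusted p = 0.10). Urea cycle and amino acid catabolism had 5 of 20 higher and 2 lower (7 and 2 adjusted over the list alone), with the urea cycle enzyme CPS1 at 1.13 ± 0.26. The drug and urea cycle lists both had adjusted p = 0.15 with an estimated correlation.

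Targets of ATF4 and the integrated stress response were lower in 9 of 30 cases and higher in 1 (10 and 1 adjusted over the list alone), including the stress cytokine GDF15 (-1.49 ± 0.24), ATF3 (-1.77 ± 0.34) and DDIT4 (-1.38 ± 0.27). They had adjusted p = 0.37 with an estimated correlation. The p53 targets were lower in 5 of 24 cases (6 lower and 1 higher adjusted over the list alone), with CDKN1A at -1.55 ± 0.22 (adjusted p = 0.13 with an estimated correlation). HIF targets had 6 of 30 members lower and 3 higher (6 and 4 adjusted over the list alone), with NDRG1 at -1.26 ± 0.23 and the glucose transporter SLC2A3 at -1.58 ± 0.30 (adjusted p = 0.53 with an estimated correlation). Without the 2 libraries that stood apart camera with the preset correlation no longer called the HIF list (adjusted p = 0.10). In lysosome and autophagy 4 of 19 members fell, as adjusted over the list alone, including GABARAPL1 (-1.39 ± 0.21) and the autophagy receptor SQSTM1 (-0.88 ± 0.21), with adjusted p = 0.22 with an estimated correlation. Plasmax-TE replicate 1, the library that stood apart, had 163 CPM of the ATF4 target ASNS against 418 and 586 CPM in the other Plasmax-TE libraries. TFRC (-0.22 ± 0.23), FTH1 (-0.16 ± 0.13), FTL (-0.16 ± 0.17), SLC11A2 (0.20 ± 0.16) and SLC40A1 (0.23 ± 0.33) did not pass, with adjusted p between 0.46 and 0.70 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

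Plasmax-TE+Fe was set against Plasmax-TE to see which transcripts responded to iron when the other trace elements stayed out. CYP1A1 rose from 2.13 ± 1.03 to 13.6 ± 6.64 CPM (log2 fold change 2.60 ± 0.45, 6.08-fold). CHST15, a chondroitin sulfotransferase, rose by 1.77 ± 0.36, TCIM, a regulator of Wnt signalling, by 1.39 ± 0.27, and VPS37A, a component of the endosomal sorting complex, by 1.17 ± 0.24. So did the adhesion scaffold NEDD9 by 1.13 ± 0.21, the Notch ligand JAG1 by 1.12 ± 0.19, the TWEAK receptor TNFRSF12A by 1.01 ± 0.19 and the ribonuclease RNASET2 by 0.87 ± 0.17. AGXT (ENSG00000172482) fell from 12.6 ± 2.06 to 2.87 ± 0.997 CPM (-2.12 ± 0.39) and SULT2A1 (ENSG00000105398) from 92.3 ± 11.3 to 43.8 ± 7.34 CPM (-1.07 ± 0.19). Further falls were those of the ubiquitin ligase TRIM50 (-1.86 ± 0.32), SPTLC3, a subunit of serine palmitoyltransferase (-1.29 ± 0.23), ALDH6A1, a mitochondrial enzyme of valine breakdown (-1.04 ± 0.20), FGB (-0.99 ± 0.20) and the citrate transporter SLC13A5 (-0.98 ± 0.19). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of these 15 genes lay between 0.024 and 0.044. As the rule took only genes whose libraries did not overlap, each necessarily went the same way in all 3 runs of library numbers.

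The test called 27 genes, 9 higher and 18 lower with iron, of which 14 had a log2 fold change of at least 1. With the library-number block it called 152 (51 higher, 101 lower, all 27 included), and with Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2 both left out, chosen after seeing the data, 99 (42 higher, 57 lower). DESeq2 called 71 genes, and edgeR fitted to only the 6 libraries of these media called 0, with 776 genes at an unadjusted p under 0.05, where DESeq2 called 33 and limma-voom 0. Leaving out any 1 of 4 libraries ended every call. In edgeR 0 genes passed without Plasmax-TE replicate 2, Plasmax-TE replicate 3, Plasmax-TE+Fe replicate 1 or Plasmax-TE+Fe replicate 3 (897, 981, 736 and 549 at an unadjusted p under 0.05), where limma-voom called 0, 0, 1 and 0 and DESeq2 51, 40, 26 and 10. Without any change, a share of about 0.05 of the genes tested would be expected at such an unadjusted p. Without Plasmax-TE+Fe replicate 2 edgeR called 229. That fit kept Plasmax-TE replicate 1, the other library that stood apart, in Plasmax-TE. Its deviation could not be told apart there from a change with iron. On data simulated for this comparison the test recovered 10.4% of genes changed by a log2 fold change of 0.5, 59.7% at 1 and 89.4% at 2, so changes of less than 1 were often not detectable.

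Camera with its preset correlation called 12 of 27 lists between Plasmax-TE+Fe and Plasmax-TE, 5 higher and 7 lower, and none of these calls held with an estimated correlation. Cholesterol synthesis was lower, with 1 of 22 members lower over all genes and 11 adjusted over the list alone (median -0.54, adjusted p = 0.086 with an estimated correlation). In fatty acid oxidation and ketogenesis 2 of 17 members fell (6 lower and 1 higher adjusted over the list alone), FABP1 by 0.94 ± 0.16 and the peroxisomal thiolase ACAA1 by 0.86 ± 0.16 (adjusted p = 0.056 with an estimated correlation, and adjusted p = 0.027 with an estimated correlation and the block). Hepatocyte secreted proteins and markers were lower, with 1 of 33 members over all genes and 15 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation and adjusted p = 0.027 with the block added). Acute phase and complement genes were lower as well, with 1 of 16 and 7 adjusted over the list alone (adjusted p = 0.18 and adjusted p = 0.016). With an estimated correlation and the 2 libraries that stood apart left out, these lists had adjusted p = 0.19, adjusted p = 0.23 and adjusted p = 0.19, in the order fatty acid oxidation, hepatocyte proteins and acute phase. FGB, a member of both hepatocyte and acute phase lists, passed. Fatty acid synthesis (0 of 14 over all genes, 2 lower adjusted over the list alone, median -0.23), S phase and DNA replication (0 of 34 by both counts, median -0.23) and G2/M and mitosis (0 of 31 by both counts, median -0.30) were also lower as lists. They had adjusted p = 0.14, adjusted p = 0.51 and adjusted p = 0.32 with an estimated correlation. Higher with iron were the HIF targets (0 of 30 over all genes, 9 adjusted over the list alone, median 0.42, adjusted p = 0.21 with an estimated correlation). The targets of ATF4 were higher too (0 of 30, 4 adjusted over the list alone, median 0.36, adjusted p = 0.32 with an estimated correlation). Glycolysis (0 of 14 by both counts, median 0.27), NRF2 targets (0 of 23 by both counts, median 0.13) and immediate early and heat shock genes (0 of 14, 1 adjusted over the list alone, median 0.17) were higher as lists. Their values were adjusted p = 0.26, adjusted p = 0.41 and adjusted p = 0.21 with an estimated correlation. Camera with the preset correlation no longer called the immediate early and heat shock genes when the 2 libraries that stood apart were left out (adjusted p = 0.30). In those libraries glycolysis had a median log2 difference of -0.44 from the other 4 of the same media (2 of 14 members above 0). The median was -0.47 for NRF2 targets (3 of 23), -0.46 for ATF4 targets (7 of 30) and -0.40 for S phase genes (8 of 34). These medians were larger in size than the median changes with iron. So was that of acute phase genes, at 0.39 (14 of 16) against -0.32 with iron. That of hepatocyte proteins was smaller, at 0.14 (22 of 33) against -0.36 with iron.

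The 6 iron genes named in advance did not pass between these media. HAMP stood at 80.6 ± 29.1 CPM without and 76.4 ± 10.5 CPM with iron (-0.08 ± 0.23), TFRC at 72.2 ± 18.6 and 59.6 ± 22.4 CPM (-0.27 ± 0.24). FTH1 differed by 0.08 ± 0.13, FTL by 0.08 ± 0.17, SLC11A2 by -0.28 ± 0.16 and SLC40A1 by 0.40 ± 0.31. Their adjusted p lay between 0.62 and 0.96 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and between 0.46 and 0.95 with the library-number block. TFRC was lower and FTH1 and SLC40A1 were higher with iron in each of the 3 runs of library numbers. These amounts did not pass in either fit. In the middle run TFRC hardly differed, at 76 CPM in Plasmax-TE replicate 2 and 75.2 CPM in Plasmax-TE+Fe replicate 3. HAMP, FTL and SLC11A2 went both ways across the runs. In the iron list 0 of 21 members passed over all genes and 2 fell adjusted over the list alone, TFR2 (-0.94 ± 0.22) and FBXL5 (-1.26 ± 0.29), and camera did not call the list (adjusted p = 0.051). With the library-number block these 2 genes passed over all genes in edgeR's test, TFR2 at adjusted p = 0.0053 and FBXL5 at adjusted p = 0.018.

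**Figure D3:**
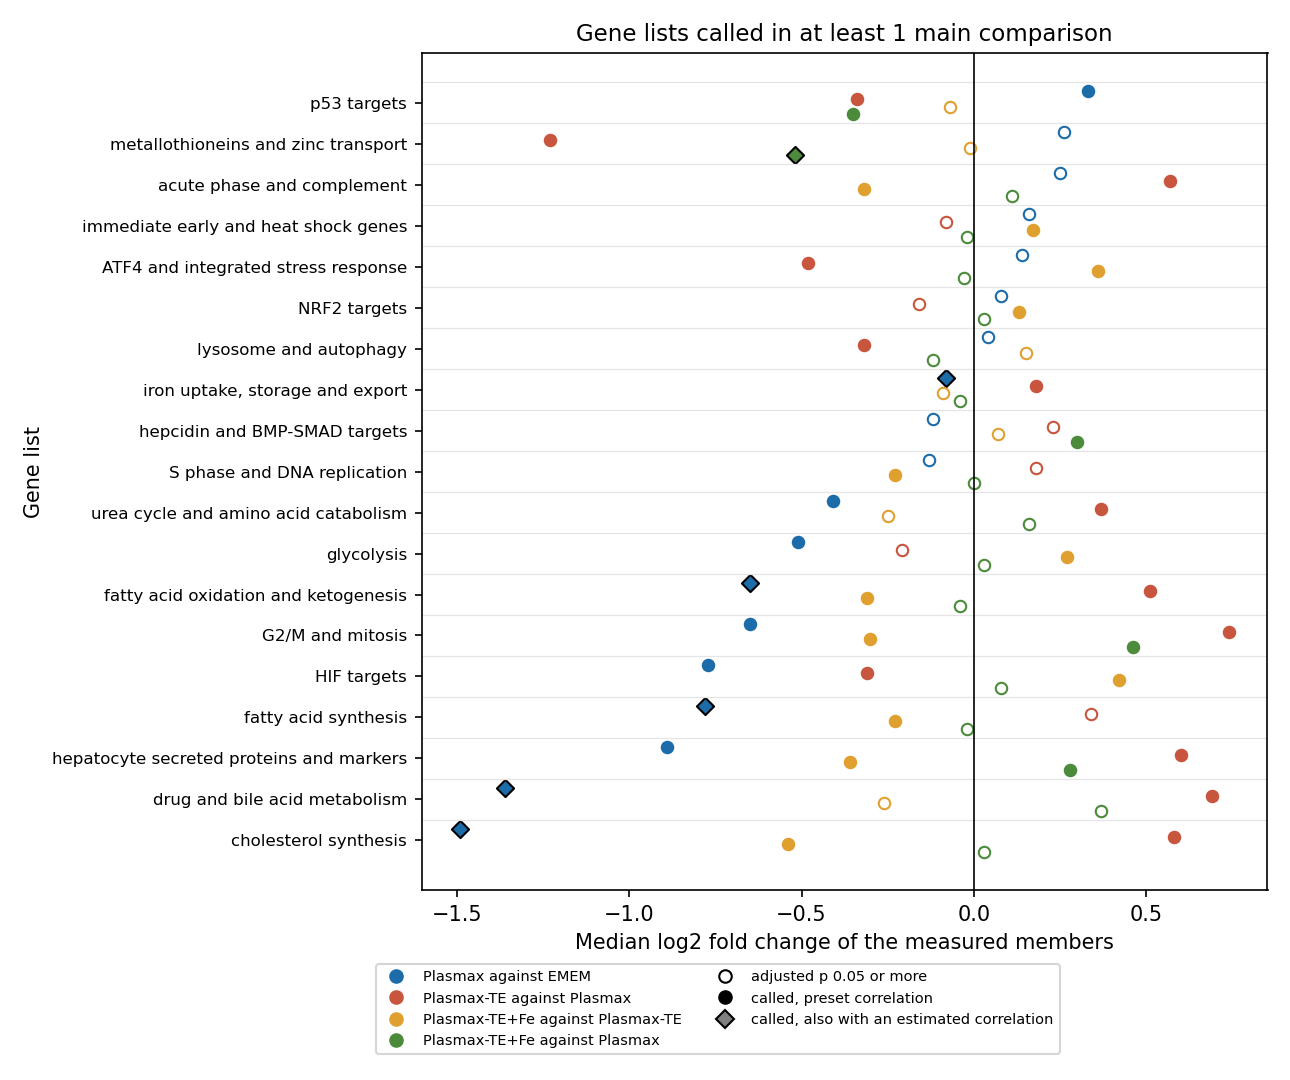
Median log2 fold change of the measured members of each gene list that camera called in at least 1 of the 4 main comparisons. Colour gives the comparison, open circles lists that were not called, filled circles calls with the preset correlation and diamonds calls that also held with an estimated correlation; cholesterol synthesis lies at -1.49 for Plasmax against EMEM, 0.58 for Plasmax-TE against Plasmax and -0.54 for Plasmax-TE+Fe against Plasmax-TE.

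Plasmax-TE+Fe was then set against Plasmax, media that differ in the trace elements other than iron as far as the labels say. HAMP remained higher, at 76.4 ± 10.5 against 7.05 ± 1.07 CPM (3.44 ± 0.31, 10.9-fold), and SELENOW lower, at 42.3 ± 3.21 against 161 ± 61.0 CPM (-1.93 ± 0.24). The metallothioneins MT1G (-2.51 ± 0.29), MT1F (ENSG00000198417, -2.46 ± 0.26), MT1E (-1.65 ± 0.22) and MT2A (-1.60 ± 0.24) were lower. So were CYP1A1 (-2.59 ± 0.27), EMP1 (-2.70 ± 0.36), PMAIP1 (-1.87 ± 0.29), GPRC5A (-1.85 ± 0.41) and the muscle atrophy ubiquitin ligase FBXO32 (-1.71 ± 0.35). LOX (2.52 ± 0.46), G6PC (2.12 ± 0.38), PCOLCE2, an enhancer of procollagen processing (1.94 ± 0.42), MAT2A, which makes S-adenosylmethionine (1.83 ± 0.32), DEPP1 (1.66 ± 0.25), IGFBP1, a binding protein of insulin-like growth factors (1.64 ± 0.25), and the steroid dehydrogenase HSD17B2 (1.62 ± 0.18) were higher. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 5.3e-06 for HAMP, 1.3e-04 for SELENOW, 7.6e-05 for MT1G, 2.3e-05 for MT1F and CYP1A1, 4.0e-05 for HSD17B2 and at most 0.030 for the others named. The metallothionein genes are near-identical copies, and how shared reads were counted is not given in the sources used here, so the split between single MT1 genes is uncertain.

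The test called 126 genes, 53 higher and 73 lower, of which 71 had a log2 fold change of at least 1. The count was 372 with the library-number block, 77 in a fit to the 6 libraries of these media, 31 without Plasmax replicate 2, 71 without Plasmax-TE+Fe replicate 1 and 82 without Plasmax-TE+Fe replicate 2. Camera called 5 lists. Metallothioneins and zinc transport had 5 of 11 members lower (6 lower and 1 higher adjusted over the list alone), and this call held (adjusted p = 0.022 with an estimated correlation). The hepcidin and BMP-SMAD list was higher with 1 of 13 members, HAMP, over all genes and 4 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation, and adjusted p = 0.022 when the 2 libraries that stood apart were left out as well). Hepatocyte secreted proteins and markers were higher in 5 of 33 cases (11 adjusted over the list alone), with ALB at 0.94 ± 0.11 and the retinol carrier RBP4 at 0.64 ± 0.13 (adjusted p = 0.33 with an estimated correlation). G2/M and mitosis was higher with 1 of 31 members by both counts, here adjusted over the list alone as well, CENPE (0.82 ± 0.18), with adjusted p = 0.37 with an estimated correlation. The p53 targets were lower in 2 of 24 cases (4 adjusted over the list alone), ZMAT3 (-0.67 ± 0.15) and RRM2B (-0.81 ± 0.19), with adjusted p = 0.054 with an estimated correlation. TFRC (-0.49 ± 0.24), FTH1 (-0.08 ± 0.13), FTL (-0.08 ± 0.17), SLC11A2 (-0.09 ± 0.16) and SLC40A1 (0.64 ± 0.32) did not pass in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p between 0.37 and 0.89).

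How far adding iron moved genes back was measured on the 1176 genes called between Plasmax-TE and Plasmax. Of these, 25 were called in the opposite direction and 0 in the same direction when iron was added, and 120 were still called between Plasmax-TE+Fe and Plasmax, all in the direction of the first change. By sign alone 1122 (95.4%) moved back with iron, and the median share of the change undone was 0.43. The comparisons share the Plasmax-TE libraries, and in 20 simulations with no effect of iron 69.6% moved back on average (at most 71.1%), the median share undone was 0.13 (at most 0.143) and 0 genes were called in the opposite direction. The simulations drew libraries independently, although deviations of Plasmax-TE and Plasmax-TE+Fe libraries of the same run correlated at 0.53, 0.22 and 0.38. AREG, chosen here after its values were seen, stood at 682 ± 145 CPM in Plasmax, 58.9 ± 30.2 CPM without trace elements and 242 ± 152 CPM with iron (2.03 ± 0.42 against Plasmax-TE, with libraries that overlapped between these media). With the library-number block 140 of 1859 genes were called in the opposite direction and 336 were still called. DESeq2 put the first of these counts at 61. Leaving out Plasmax-TE+Fe replicate 2 gave 196 genes in the opposite direction and 71 still called, leaving out Plasmax replicate 2 gave 15 and 30, leaving out Plasmax replicate 3 gave 41 in the opposite direction, and leaving out Plasmax-TE+Fe replicate 1 gave 68 still called. The 196 came with Plasmax-TE replicate 1, which also stood apart, still in its group. With both libraries left out, chosen after seeing the data, 91 genes were called in the opposite direction. In edgeR 0 genes were called in the opposite direction without Plasmax-TE replicate 2, Plasmax-TE replicate 3, Plasmax-TE+Fe replicate 1 or Plasmax-TE+Fe replicate 3, the libraries without which no gene passed when iron was added.

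Across the 10459 genes the log2 fold changes of Plasmax-TE against Plasmax and of Plasmax-TE+Fe against Plasmax-TE had Pearson's r of -0.68 and Spearman's rho of -0.66, where 20 simulations of unchanged groups gave a mean r of -0.50 from the shared libraries. The covariance was -0.135 against a simulated -0.043, a difference of -0.092. The changes of Plasmax against EMEM and of Plasmax-TE against Plasmax had r = -0.73 (simulated -0.51), and a covariance of -0.284 against -0.043. There were 798 genes called in opposite directions, such as AREG and CYP1A1, where independent lists of these sizes would share 125.5, against 13 called in the same direction. The changes of Plasmax-TE and of Plasmax-TE+Fe, each against Plasmax, had r = 0.78 (simulated 0.51), a covariance of 0.177 against 0.043 and 120 shared calls in the same direction against 7.1 for independent lists. The 3 shared libraries are too few to be divided between the comparisons, so part of these overlaps may come from the shared libraries. Plasmax against EMEM and Plasmax-TE+Fe against Plasmax-TE share no library. Their log2 fold changes had r = 0.42 (jackknife SE 0.078) and rho = 0.40, where the simulations gave r between -0.02 and 0.02, with a covariance of 0.104 against 0. These simulations also took libraries of the same run as independent. Here 21 genes were called in the same direction and 1 in the opposite one, against 3.0 and 2.8 for independent lists. AREG, CYP1A1, AGXT and SULT2A1 went the same way in both. Genes are not independent replicates, so these correlations carry no p-value.

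Plasmax-TE and Plasmax-TE+Fe were also set against EMEM. TXNIP was higher in both, at 261 ± 58.1 and 323 ± 29.4 CPM against 7.16 ± 1.21 CPM (5.15 ± 0.25 and 5.46 ± 0.25), as was SERPINA3, an acute phase protease inhibitor (3.57 ± 0.38 and 3.50 ± 0.38). In Plasmax-TE the gene ENSG00000276980, which has no symbol in the sources used here (3.61 ± 0.48), and RNF125 (3.17 ± 0.42) were also among the highest. The lowest were TNS1 (-3.80 ± 0.45), MT1G (-2.71 ± 0.28), the glycolytic regulator PFKFB3 (-2.68 ± 0.64) and MT1F (-2.67 ± 0.23). In Plasmax-TE+Fe CSTA rose by 3.08 ± 0.30, and MT1F (-3.82 ± 0.25), AGXT (-3.76 ± 0.34) and MT1G (-3.34 ± 0.29) were among the genes that fell most. ARRDC4 stood at 6.53 ± 1.90 CPM in Plasmax-TE+Fe against 0.570 ± 0.654 CPM in EMEM. TFRC was lower in both, by a log2 fold change of -1.10 ± 0.23 and -1.37 ± 0.23, and HAMP did not pass (0.81 ± 0.24 and 0.73 ± 0.24). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of TFRC was 0.0068 and 5.9e-04, and that of HAMP 0.056 and 0.058, or 0.0066 and 0.0063 with the library-number block. The test called 503 genes (169 higher, 334 lower) in Plasmax-TE and 1009 (384 higher, 625 lower) in Plasmax-TE+Fe, and 829 and 1569 with the block. Without EMEM replicates 1, 2 and 3 the counts were 293, 284 and 259 in Plasmax-TE and 628, 666 and 606 in Plasmax-TE+Fe. They were 294 in Plasmax-TE without Plasmax-TE replicate 2 and 651 in Plasmax-TE+Fe without Plasmax-TE+Fe replicate 3.

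Between Plasmax-TE and EMEM camera called 11 lists, of which 7 held with an estimated correlation. HIF targets were lower in 20 of 30 cases (23 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation) and glycolysis in 6 of 14 (10 adjusted over the list alone, adjusted p = 0.029). With the 2 libraries that stood apart left out glycolysis had adjusted p = 0.065 with an estimated correlation. Cholesterol synthesis was lower in 14 of 22 cases (16 adjusted over the list alone, adjusted p = 0.0075) and metallothioneins and zinc transport in 5 of 11 (6 lower and 2 higher adjusted over the list alone, adjusted p = 0.021). Fatty acid synthesis and drug and bile acid metabolism were lower too, both with adjusted p = 0.0075 with an estimated correlation. Acute phase and complement genes were higher in 10 of 16 cases and lower in 1 (12 and 1 adjusted over the list alone), with adjusted p = 0.029 with an estimated correlation. Fatty acid oxidation, ATF4 targets and lysosome genes were lower and heme synthesis and iron-sulfur assembly higher with the preset correlation but not with an estimated one (adjusted p = 0.27, adjusted p = 0.81, adjusted p = 0.31 and adjusted p = 0.079 with an estimated correlation). Without the 2 libraries that stood apart camera with the preset correlation no longer called ATF4 targets (adjusted p = 0.36) or lysosome genes (adjusted p = 0.10). In those libraries ATF4 targets had a median log2 difference of -0.46 from the other 4 libraries of the same media. Between Plasmax-TE+Fe and EMEM 5 of 13 calls held, all lower. Cholesterol synthesis, with 18 of 22 members lower (20 adjusted over the list alone), fatty acid synthesis and drug and bile acid metabolism had adjusted p = 0.0023 with an estimated correlation. Fatty acid oxidation had adjusted p = 0.019 and the iron list adjusted p = 0.042, and both had adjusted p = 0.057 with an estimated correlation when the 2 libraries that stood apart were left out. HIF targets, glycolysis, metallothioneins, G2/M genes, hepatocyte markers and the urea cycle list were lower and acute phase and nucleotide synthesis genes higher with the preset correlation but not with an estimated correlation alone. In this order they had adjusted p = 0.13, adjusted p = 0.21, adjusted p = 0.072, adjusted p = 0.68, adjusted p = 0.16, adjusted p = 0.097, adjusted p = 0.31 and adjusted p = 0.29 with an estimated correlation. With an estimated correlation and the block metallothioneins (adjusted p = 0.024), hepatocyte markers (adjusted p = 0.045) and acute phase genes (adjusted p = 0.035) passed. With an estimated correlation and the 2 libraries that stood apart left out they did not (adjusted p = 0.086, adjusted p = 0.21 and adjusted p = 0.36). Without the 2 libraries that stood apart camera with the preset correlation no longer called G2/M genes (adjusted p = 0.30) or the urea cycle list (adjusted p = 0.098).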

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

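The alternatives were chosen before the data were examined, except leaving out Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2 together and camera with the library-number block. No result reversed, and results that were not called carry no direction label. Of the named genes' log2 fold changes, DESeq2 left 515 on their side of the threshold, moved 14 past it and 8 below it. Leaving out single libraries gave 6095 values on the same side, 77 newly past the threshold and 343 no longer past it. With the library-number block 2835 genes differed among the media. There 1859 genes were called for Plasmax-TE against Plasmax, 152 for Plasmax-TE+Fe against Plasmax-TE, 372 for Plasmax-TE+Fe against Plasmax, 829 for Plasmax-TE against EMEM and 1569 for Plasmax-TE+Fe against EMEM. It gave 140 genes changed in the opposite direction with iron and 336 still different. The pair of libraries left out gave 99 genes for Plasmax-TE+Fe against Plasmax-TE and 91 in the opposite direction with iron. DESeq2 gave 71 and 61, and a fit to the 6 libraries compared gave 0 for Plasmax-TE+Fe against Plasmax-TE and 77 for Plasmax-TE+Fe against Plasmax. Without single libraries the counts ran from 1275 to 2465 among the media and 1489 to 2642 for Plasmax against EMEM. They ran from 477 to 1577 for Plasmax-TE against Plasmax (780 without Plasmax replicate 1, 477 without Plasmax replicate 2, 744 without Plasmax-TE replicate 1), and from 0 to 229 for Plasmax-TE+Fe against Plasmax-TE (17 without Plasmax replicate 2, 47 without Plasmax replicate 3, 229 without Plasmax-TE+Fe replicate 2). The range was 31 to 170 for Plasmax-TE+Fe against Plasmax (31 without Plasmax replicate 2, 71 and 82 without Plasmax-TE+Fe replicates 1 and 2) and 259 to 678 for Plasmax-TE against EMEM (293, 284 and 259 without EMEM replicates 1, 2 and 3, 294 without Plasmax-TE replicate 2). It was 606 to 1224 for Plasmax-TE+Fe against EMEM (628, 666 and 606 without EMEM replicates 1, 2 and 3, 651 without Plasmax-TE+Fe replicate 3). For Plasmax-TE+Fe against Plasmax-TE edgeR called 0 genes without Plasmax-TE replicate 2, Plasmax-TE replicate 3, Plasmax-TE+Fe replicate 1 or Plasmax-TE+Fe replicate 3. There were 897, 981, 736 and 549 genes at an unadjusted p under 0.05, where limma-voom called 0, 0, 1 and 0 and DESeq2 51, 40, 26 and 10. In the fit to 6 libraries these counts were 776, 0 and 33. Without any change, a share of about 0.05 of the genes tested would be expected at an unadjusted p under 0.05. The genes in the opposite direction with iron ran from 0 to 196 (15 without Plasmax replicate 2, 41 without Plasmax replicate 3, 196 without Plasmax-TE+Fe replicate 2, and 0 without the same 4 libraries). Those still different ran from 30 to 144 (30 without Plasmax replicate 2, 68 and 71 without Plasmax-TE+Fe replicates 1 and 2). The correlation of Plasmax against EMEM with Plasmax-TE+Fe against Plasmax-TE ran from 0.34 (without Plasmax-TE replicate 1) to 0.43. In the order Plasmax against EMEM, Plasmax-TE against Plasmax, Plasmax-TE+Fe against Plasmax-TE, Plasmax-TE+Fe against Plasmax, Plasmax-TE against EMEM and Plasmax-TE+Fe against EMEM, an estimated correlation left 5, 0, 0, 1, 7 and 5 called lists. The library-number block with an estimated correlation left 5, 3, 3, 1, 7 and 8, where for Plasmax against EMEM the iron list was lost and hepatocyte proteins came in. Single libraries left out gave 11 to 12, 10 to 14, 9 to 17, 5 to 8 (8 without Plasmax-TE+Fe replicate 2), 7 to 12 (7 without EMEM replicate 3) and 12 to 14. Mixed fry called 26 lists for Plasmax against EMEM, 23 for Plasmax-TE against Plasmax, 15 for Plasmax-TE+Fe against Plasmax, 23 for Plasmax-TE against EMEM and 21 for Plasmax-TE+Fe against EMEM. Directional fry called 4 for Plasmax-TE+Fe against Plasmax-TE. Fewer libraries leave fewer degrees of freedom, but this does not account for counts that rose, such as the 229 without Plasmax-TE+Fe replicate 2. There Plasmax-TE replicate 1 stayed in Plasmax-TE, so its deviation could not be told apart from a change with iron. Mixed fry by construction counts changes in either direction. For the other shifts, those rises included, the cause was not tested. The replicate block gave 1662 genes among the media, 2079, 1024, 19, 105, 440 and 926 genes in the order above and 19 in the opposite direction with iron, all within 1.5 times the counts reported. Replicate numbers and runs coincide in EMEM, Plasmax and Plasmax-TE, where deviations from the group mean correlated between 0.04 and 0.17 in pairs with the same number. Replicate numbers did not pair the Plasmax-TE+Fe libraries with these (-0.43 to 0.15, with a mean of -0.007 over all 18 pairs), while pairs of the same run of library numbers correlated between 0.03 and 0.53 (mean 0.143). At these depths 1 count was worth between 0.419 and 0.640 CPM, and 10.4% of simulated changes of 0.5 were recovered with 3 libraries per medium, but depth was not varied in that simulation, so its part in the recovery is not known.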

Other observations

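The tests of the shared run, of random blocks and of HAMP against the acute phase genes were chosen only after the result was seen. Selenoproteins moved both ways: of 18 measured, 6 rose and 5 fell in Plasmax against EMEM (6 and 6 adjusted over the list alone). SELENOW stood at 2.65 ± 0.25 and GPX1 at 1.56 ± 0.17 against GPX3 at -2.48 ± 0.22 and SELENOP at -1.47 ± 0.19, and camera did not call the list (adjusted p = 0.99). In Plasmax-TE against Plasmax SELENOW fell by 2.04 ± 0.24 and GPX1 by 0.52 ± 0.16, while SEPHS2 (0.96 ± 0.16), GPX3 (1.18 ± 0.24) and SELENOP (0.71 ± 0.19) rose. Of 13 progenitor, fetal and biliary markers 4 rose and 3 fell in Plasmax against EMEM (5 and 3 adjusted over the list alone). KRT19 (2.27 ± 0.27) and SOX4 (2.19 ± 0.18) rose and AFP (-2.81 ± 0.15) and DLK1 (-1.25 ± 0.14) fell. These 4 changed in the other direction in Plasmax-TE against Plasmax (KRT19 -2.23 ± 0.27, SOX4 -1.37 ± 0.17, AFP 1.44 ± 0.14, DLK1 0.91 ± 0.14), while SPP1 and EPCAM, which had risen, did not pass there. Opposite signs are favoured because the comparisons share the Plasmax libraries, and this was not simulated for these genes. Camera did not call that list (adjusted p = 0.55 and 0.27).

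Among mesenchymal and matrix genes TIMP1 rose by 2.87 ± 0.24 and ACTA2 by 0.93 ± 0.20 in Plasmax against EMEM, while TGFBI fell by 1.46 ± 0.15, and camera did not call the list (adjusted p = 0.88). Camera did not call the interferon-stimulated genes as a list in any comparison, and 1 of 12 members, BST2, rose in Plasmax-TE against Plasmax (0.68 ± 0.17, also adjusted over the list alone). Lists of other cell types had too few measured members to test. The endothelial markers ESAM and TIE1, 2 of 11, rose by 2.81 ± 0.29 and 2.95 ± 0.61 in Plasmax and fell by 2.19 ± 0.27 and 1.96 ± 0.53 without trace elements. Of 3 measured fibroblast markers, from a list of 15, PDGFRB fell by 3.02 ± 0.45 in Plasmax, and the 1 measured of 16 leukocyte markers, LYZ, fell by 0.70 ± 0.24. None of the 13 mitochondrially encoded messages was measured.

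Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2 deviated together from their groups. Compared with the other 4 libraries of these media they had less ALDH1L2 (-2.35), SLC2A1 (-2.14), CTH (-1.72), RRM2 (-1.61), ASNS (-1.60), PHGDH (-1.58) and MTHFD2 (-1.28), and more SNORD13 (3.11) and HAL (2.14), genes chosen after their values were seen. An exchange of their labels is argued against, since 90.9% of the genes called between the media without them (90 of 99, exact 95% interval 83.4 to 95.8) had the same sign between the pair. So is depth, since after thinning to the lowest total their deviations still correlated at 0.50 (0.53 before). A shared run of library numbers may contribute: with these media's pairs left out, the real runs had a mean correlation of 0.096, and no other assignment of libraries to runs reached it (1, the real one, as high, and 0.066 the next). What differed between runs is not in the labels, and no biological explanation was tested.

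Few genes were called between Plasmax-TE+Fe and Plasmax-TE in the fit without a block. Spread between library-number runs may account for part of this, since the real runs as a block gave 152 genes, and 0 of 99 random assignments of libraries to blocks gave as many (highest 133, median 18). The real runs put Plasmax-TE replicate 1 and Plasmax-TE+Fe replicate 2, already seen to deviate together, in the same block. Random assignments were not held to this, so the test cannot separate the runs in general from this pair.

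HAMP was higher in both media without the full trace elements than in Plasmax. With the library-number block the larger of its adjusted p-values was 2.0e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In Plasmax HAMP stood at 8.15, 6.01 and 6.98 CPM in the order of the runs. In the same order it stood at 47.1, 95.3 and 99.5 CPM in Plasmax-TE and at 64.8, 79.2 and 85.2 CPM in Plasmax-TE+Fe. Each run held a library of every medium, so these values argue against a shift between whole runs as the cause. HAMP levels in Plasmax did not overlap with those in these media, so every run necessarily showed this direction. A rise shared with the acute phase genes stays open. Between Plasmax-TE+Fe and Plasmax-TE HAMP lay 1.58 of its standard errors from the median of that list, but HAMP did not pass there, so this says nothing about its rise against Plasmax. Against Plasmax the list had medians of 0.57 in Plasmax-TE and 0.11 in Plasmax-TE+Fe beside log2 fold changes of 3.52 and 3.47 for HAMP with the block. In Plasmax against EMEM HAMP fell by 2.71 ± 0.32, where the median of the list was 0.25. A rise of BMP-SMAD targets stayed open too: 0 of 8 measured targets were called higher in both comparisons by edgeR with the library-number block, but 1 and 2 were called in each, with medians of 0.20 and 0.39 and standard errors of up to 0.35. A biological effect of the trace elements other than iron remains open and was not tested beyond these comparisons.

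For the comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The highest count of the other splits was 0 beside the real 2233 for Plasmax against EMEM, 1176 for Plasmax-TE against Plasmax, 126 for Plasmax-TE+Fe against Plasmax, 503 for Plasmax-TE against EMEM and 1009 for Plasmax-TE+Fe against EMEM, where in each 1 of 10 splits, the real one, gave as many genes in edgeR. At unadjusted p < 0.05 those other splits gave at most 624, 956, 791, 627 and 839 genes, in this order. Each of them put libraries of both media on each side, so a difference between the media widened the spread and lowered the count. Their 0 is therefore not the count to be expected without a difference between media. For Plasmax-TE+Fe against Plasmax-TE 2 of 10 splits gave at least the real 27 genes. The other one gave 115, several times the real count, and put Plasmax-TE replicates 1 and 2 and Plasmax-TE+Fe replicate 2 on one side, which points to a structure of the samples, the pair described above. At an unadjusted p under 0.05 in edgeR's test this split gave 2053 genes, against 974 for the real one. Further splits with the pair on one side gave 1624 and 1159. Among 100 splits of the 12 libraries into 4 groups, 1, the real one, gave as many genes as the 1879 called. The highest of the others gave 822, so a random grouping of these libraries is argued against. The share of 1 in 100 is the lowest that these splits can give. Chance differences between cultures were not tested, since the libraries of a medium may share a culture.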
